A study of Homo sapiens with 4 samples.

How the data were processed

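RNA of 4 xenograft tumours, 2 of H187 and 2 of its ABT-737 resistant derivative H187-63AR, was measured on 1 slide of Illumina bead arrays. Per the labels' protocols, total RNA was taken from snap-frozen tumours with Trizol and column purification, checked on a Bioanalyzer, amplified with the Illumina TotalPrep kit and labelled with biotin. The submitters' processing notes name BeadStudio without a version. Groups were taken from the sample titles. Both H187-63AR titles carry the number 1, so the groups share only 1 number and no pairing was used; the H187-63AR replicates were numbered in order of deposition.

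The main table, per the file headers, holds the deposited mean bead intensity per probe with the standard error over beads, the number of beads and a detection p-value. Its name says that it was deposited without normalization or background subtraction. The number of beads, another quantity of the deposited table per the file headers, had a median of 42 or 43 per probe on each array. The deposited p-value is the scanner software's test of a probe against background, per the file headers. Median signals were 60.2 and 57.9 on the H187 arrays and 54.0 and 58.0 on the H187-63AR arrays. A second table holds the authors' processed intensity. Each of its columns was a straight line of the same array's raw signal, with slopes of 1, 1.01, 1.08 and 0.912 and intercepts of -48.6, -45.1, -43.7 and -39.1, and deviated from it by at most 0.0079 units. Its scale is therefore linear, background-subtracted, scaled between arrays and not centred, with column medians of 11.6, 13.2, 14.4 and 13.9; the name of the normalization is not given in the sources used here. All 4 arrays carry 1 slide, so slide could not act as a batch.

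Signals were corrected for background with limma 3.58.1 in R 4.3.3, by the normexp model with the background inferred from the detection p-values and an offset of 16, then quantile normalized and taken to log2. The offset understates changes of dim genes. Probes with a detection p under 0.05 on at least 2 of the 4 arrays were tested, which left 12634 of 22184. Genes were named from the platform annotation, with symbols updated by Entrez identifier through the gene table of the human reference assembly GRCh38.p14. Of the probes 19715 had 1 symbol, 0 had several and 2469 had none, and 19695 were found in the gene table. For each gene the probe with the highest mean was used, and each unnamed probe counted as its own gene, giving 11576 genes, of which 10407 were named. Of 36 called genes with several probes, 28 had all probes in the same direction and 8 had a probe of opposite sign. No build is named for the array, so no coordinates are given.

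The groups were compared with limma's lmFit and eBayes, two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over all genes, with 7.93 degrees of freedom per gene including the prior. Values are log2 fold changes, H187-63AR minus H187, ± standard error with n = 2 per group. Where a gene was undetected on both arrays of 1 group, the brighter group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among detected probes and the gene's own signal, and is given as "at least"; figures and list medians use the fitted values, and with these genes at their bounds the medians moved from 0.25 to 0.11 for endothelial, from -0.12 to -0.053 for MAPK feedback and from 0.42 to 0.32 for fibroblast and matrix genes, and those of the other 44 lists, NF-kB among them, stayed. Both tumours of 1 group lay above both of the other for 48.4% of genes, where chance gives 33.3%. The 47 gene lists were fixed before the data were examined, as were the tests of genes and lists and the rule for naming genes. So were the alternatives, except for the 2 choices named below. The 45 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01; 1 was higher and 1 lower. Camera with an estimated correlation called 0, where the preset test had 11 lists at an unadjusted p under 0.05. With an estimated correlation camera rests on few residual degrees of freedom, so it had little power to call a list. With the preset correlation it sets members against the other genes, so its p does not measure the spread between tumours. Fry called 0 in 1 direction and 24 for change in either direction.

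The rule named the 10 largest rises and 10 largest falls among called genes that were detected on both arrays of the brighter group and had separate groups; every tested BCL2 family member; from every other list up to 4 called members with the smallest p, or else the member with the smallest p as a value; and further list members only to say that they were not detected or not on the array. PSAT1 is named outside it.

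The pipeline was tested on simulated arrays drawn from the real probe means, the fitted spread of tested probes and the background read from the detection p-values. An earlier simulation with a spread taken from all probes recovered fewer changes and was replaced once its result had been seen. Changes were given to 200 of the brighter tested probes only. Of 13568 simulated genes, 0 of 61 changes of 0.5 on the log2 scale were recovered, 36.5% of 63 changes of 1 and 95.2% of 63 changes of 2, with 1 false call. The simulation gave 84 calls in all, against 343 in the real data, so its adjusted threshold was stricter. These shares may therefore understate the recovery in the real data. In 20 simulations without change, at most 1 gene was called.

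Alternatives were normexp with an offset of 50, no background correction, median scaling, cyclic loess, the authors' processed values floored at 16, no detection filter, detection p under 0.01 on all 4 arrays, a trended robust prior, the mean of a gene's probes, an adjusted p under 0.1, a 2-fold minimum, and each tumour left out in turn. The floor was chosen once the values had been seen, and 16 added to the processed values was an alternative chosen after the floored values gave no call. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.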

Results

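H187 is an established human small cell lung cancer cell line with neuroendocrine features, and H187-63AR is a derivative of it that is resistant to ABT-737, a small molecule that binds the pro-survival proteins BCL-2, BCL-XL and BCL-w. Cells of either line had been injected under the skin of nude mice, and RNA of the resulting tumours was hybridised to Illumina bead arrays. There were 2 H187 tumours and 2 H187-63AR tumours, 1 array each, and all 4 came from mice that received vehicle and not ABT-737. The comparison therefore asks how the transcripts of the resistant derivative differed from those of its parent without drug. The labels call the samples separate tumours and do not say how the mice or the injected cells were shared, so p-values concern these tumours only. They rest on the spread between the tumours, most of it pooled over genes by the limma prior (5.93 of 7.93 degrees of freedom). They hold no spread between resistant derivatives, since a single derivative was used. The arrays held 22184 probes, of which 12335 and 12315 were detected in the H187 tumours and 11964 and 12303 in the H187-63AR tumours. With 2 arrays per group, the number of arrays limits the precision. Across the 11576 genes tested, replicate tumours correlated at r = 0.987 in H187 and r = 0.988 in H187-63AR, and the 4 pairs across the groups had r between 0.969 and 0.977; these are correlations across genes, which are not independent replicates.

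Of 11576 genes, 343 changed, 182 of them higher and 161 lower in H187-63AR (limma, Benjamini-Hochberg adjusted p under 0.05). Among these, 91 were higher and 83 lower by at least 2-fold. The number depended on the processing. With the authors' processed values floored at 16, limma called 0 genes, although 1796 had an unadjusted p under 0.05. It called 19 with no detection filter and 545 with 16 added to the processed values, an alternative chosen after the 0 was seen. All 343 genes had the same direction in these 3 settings. The settings use the same arrays that chose these genes, so this is no independent support. Without H187 replicate 1 the number was 120, without H187 replicate 2 it was 332, and it was 150 and 123 without H187-63AR replicate 1 and replicate 2. With the floored values and the missing filter most calls ended. In every other processing alternative that tested them, 31 of the 49 called genes named by the rule passed. Some of the 49 calls were lost without 1 tumour, as given below.

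The largest rise in the reported setting was in NSG1, an endosomal protein of neurons, at a log2 fold change of 3.23 ± 0.27 (SE, n = 2 per group, limma adjusted p = 0.0016). FSCN1, which encodes the actin-bundling protein fascin, rose by 3.10 ± 0.35 on the log2 scale. NSG1 was detected in 1 of the 2 H187 tumours, so its value rests on a level near background. With an offset of 50 NSG1 read 2.11 and FSCN1 2.53, FSCN1 also exceeded NSG1 without background correction (2.67 against 2.36) and without H187-63AR replicate 1 (3.46 against 3.21), and the stricter detection filter did not test NSG1. SPRR2F, a cornified envelope gene with near-identical relatives, rose by 2.79 ± 0.24. PCSK1N, an inhibitor of a prohormone convertase, rose by 2.39 ± 0.46, and STMN2, a microtubule-binding stathmin of neurons, by 2.25 ± 0.40. SST, the precursor of somatostatin, was not detected in either H187 tumour and was at least 4.15-fold higher in H187-63AR. This bound holds for the reported setting, and with an offset of 50 SST read 1.22 on the log2 scale. The zinc finger gene ZNF91 rose by 2.21 ± 0.19, MT1F, a metallothionein with near-identical relatives, by 2.19 ± 0.21, PNMA2, a neuronal antigen detected in 1 of the 2 H187 tumours, by 2.12 ± 0.23, and KCNT1, a sodium-activated potassium channel, by 2.11 ± 0.16. The adjusted p-values of these 10 genes lay between 0.0015 and 0.037 (limma). The calls of STMN2 and PCSK1N were lost with either H187-63AR tumour left out, at adjusted p from 0.085 to 0.14; their SDs between the 2 H187 tumours were 1.05 and 1.24 on the log2 scale. Both were also lost with a trended robust prior, at adjusted p of 0.15 for STMN2 and 0.18 for PCSK1N, with an offset of 50 (0.071 and 0.070) and with no background correction (0.053 and 0.054). Without H187 replicate 1 they read 1.501 and 1.503, and without H187 replicate 2 they read 3.01 and 3.28.

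The largest fall in the reported setting was in PRSS1, which encodes trypsin, with a log2 fold change of -3.81 ± 0.13 (limma adjusted p = 3.5e-05), or 14.0-fold lower in H187-63AR. NELL1, a secreted glycoprotein, changed by -2.93 ± 0.43, PRSS3, another trypsin, by -2.84 ± 0.18 and DLK1, a non-canonical Notch ligand, by -2.83 ± 0.20 on its brighter probe and -1.21 on its other probe; the trypsin genes are near-identical in sequence, so their separate values are uncertain. ASTN2, a neuronal membrane protein detected in 1 of the 2 H187-63AR tumours, changed by -2.52 ± 0.23, CEL, the bile salt-stimulated lipase of pancreas and milk, by -2.45 ± 0.24, and the transcription factor gene FOXA2 by -2.45 ± 0.23. GRP, which encodes gastrin-releasing peptide, changed by -2.25 ± 0.27 and the transcription factor gene CEBPD by -2.25 ± 0.35. MGMT, the enzyme that repairs alkylated guanine in DNA, was not detected in either H187-63AR tumour and was at least 3.13-fold lower there. This bound too holds for the reported setting, and with an offset of 50 MGMT read -1.24 on the log2 scale. The adjusted p-values of these 10 genes lay between 3.5e-05 and 0.019 (limma). NELL1 was no longer past the threshold without H187 replicate 1 (adjusted p = 0.054) or with a trended robust prior (0.10), and CEBPD without H187-63AR replicate 2 (adjusted p = 0.089), with an offset of 50 (0.081) or with no background correction (0.056).

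**Figure D1:**
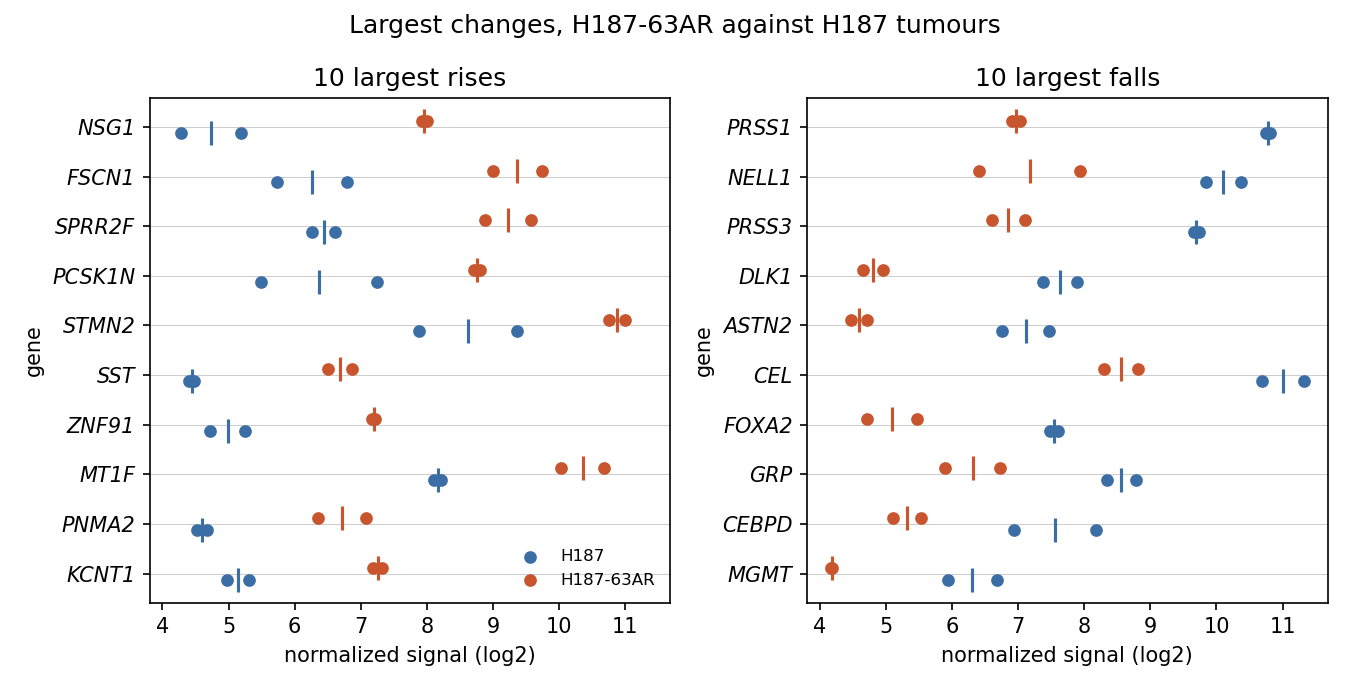
Normalized log2 signal of the 10 genes with the largest rises (left) and the 10 with the largest falls (right) in H187-63AR tumours; each point is 1 tumour, blue for H187 and orange for H187-63AR, and each bar is a group mean. For each gene both tumours of 1 group lay above both of the other, and the H187 tumours lay apart most for PCSK1N and STMN2.

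Of the tested BCL2 family genes, which include those encoding the targets of ABT-737, BCL2 alone passed the test. Its brighter probe was lower in H187-63AR, with a log2 fold change of -0.73 ± 0.14 (limma adjusted p = 0.035) or 1.66-fold. Its dimmer probe gave 0.14, and the mean of both probes gave -0.30 at adjusted p = 0.31. The BCL2 call was also lost without any 1 of the 4 tumours, at adjusted p from 0.060 to 0.17. BCL2L1, which encodes BCL-XL, had a log2 fold change of 0.20 ± 0.13 and BCL2L2, which encodes BCL-w, 0.090 ± 0.14. MCL1, a pro-survival relative that ABT-737 binds poorly, had 0.16 ± 0.17. None of these 3 passed the test. Without H187 replicate 1 BCL2L2 read 0.0089 and MCL1 -0.062, and without H187 replicate 2 they read 0.18 and 0.39; with 16 added to the processed values BCL2L1 read 0.13 and BCL2L2 0.052. BCL2A1 and BCL2L10 were not detected on any array. Of the 4 pro-survival members tested, 1 was lower, both over all genes and adjusted over the list alone.

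None of the 5 BAX-type members passed, with BAX at 0.077 ± 0.16, BAK1 at -0.090 ± 0.15, BCL2L13 at 0.11 ± 0.15 and BCL2L14 at -0.025 ± 0.13. All 4 turned direction with a tumour left out: BAX read -0.11 and BAK1 -0.23 without H187-63AR replicate 1, against 0.26 and 0.053 without H187-63AR replicate 2, and BCL2L13 read -0.015 and BCL2L14 -0.060 without H187 replicate 1, against 0.23 and 0.0084 without H187 replicate 2. BOK was not detected in H187-63AR and was at least 1.12-fold lower there, without passing. None of the 8 BH3-only members passed over all genes tested. The largest values in that group were BIK at 0.66 ± 0.16 (limma adjusted p = 0.080) and BMF at -0.91 ± 0.28 (adjusted p = 0.14). BMF read -0.51 without H187-63AR replicate 2, -1.31 without H187-63AR replicate 1 and -0.53 with an offset of 50. Adjusted over the list alone, 1 BH3-only member was higher and 1 lower. PMAIP1, which encodes NOXA, had -0.28 ± 0.14, BID 0.27 ± 0.14, BNIP3L 0.24 ± 0.13, BNIP3 -0.17 ± 0.22, BAD -0.16 ± 0.15 and BBC3, which encodes PUMA, 0.030 ± 0.14. Without H187 replicate 1 BID read 0.15, BAD -0.041 and BNIP3 0.15, and without H187 replicate 2 PMAIP1 read -0.17, BAD -0.28 and BNIP3 -0.49. BBC3 read -0.048 without H187-63AR replicate 1 and 0.11 without H187-63AR replicate 2. HRK was not detected, and BCL2L11, which encodes BIM, was detected on at most 1 array. In the simulated arrays, with 2 per group and the reported setting, none of 61 changes of 0.5 on the log2 scale were recovered. Changes were simulated only in brighter genes, and dimmer family members such as BAX and BAK1 lay outside that range. The simulation also gave fewer calls than the real data (84 against 343), so its adjusted threshold was stricter. In the real data BIK at 0.66 did not pass either. The absence of a call in this family therefore does not exclude changes of about 0.5.

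**Figure D2:**
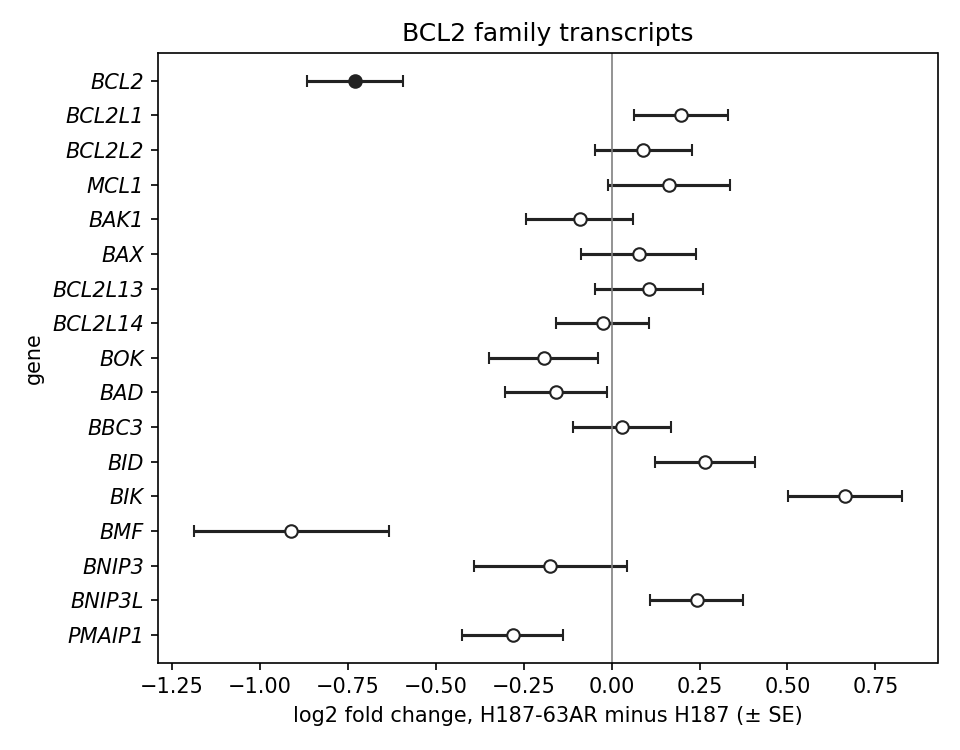
Log2 fold change of each tested BCL2 family gene, H187-63AR minus H187, with its standard error (n = 2 per group); the filled point passed the test and open points did not. BCL2, at -0.73, is the filled point, and BIK and BMF lie farthest from 0 among the open ones; the fitted value is drawn for BOK, which was undetected in H187-63AR.

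Elsewhere in the apoptosis machinery no call was made. None of the 13 tested caspases and mitochondrial factors passed, with APAF1, the scaffold of the apoptosome, at -0.51 ± 0.13 (limma adjusted p = 0.092). None of the 5 tested inhibitor of apoptosis genes passed, with BIRC2 at 0.25 ± 0.13. None of the 5 tested death receptor genes passed over all genes and 1 was higher adjusted over the list alone; TNFRSF1B, a TNF receptor, was not detected in H187 and was at least 1.31-fold higher in H187-63AR, without passing. Among p53 target genes 1 of 16 was lower, GDF15, a stress-induced cytokine, at -1.07 ± 0.13 (adjusted p = 0.0068).

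The neuroendocrine list changed in both directions. Of 29 tested members, 5 were higher and 2 lower, with 7 and 4 adjusted over the list alone. RTN1, a reticulon of neuroendocrine cells, rose by 1.94 ± 0.19 and ELAVL3, a neuronal RNA-binding protein, by 1.65 ± 0.16 on the log2 scale (limma adjusted p = 0.0027 for both), as STMN2 did, whereas FOXA2 and GRP were lower as given above. No shift of the list as a whole was called, at a median log2 fold change of 0.030 (camera adjusted p = 0.37). This median was 0.090 and 0.015 without H187 replicate 1 and replicate 2, 0.083 and 0.20 without H187-63AR replicate 1 and replicate 2, and -0.042 with no detection filter, none of them called. Of 19 neuronal and synaptic genes, 3 were higher and none lower, with 4 higher and 1 lower adjusted over the list alone. DCX, the microtubule-binding doublecortin, rose by 1.95 ± 0.23 on its brighter probe and read -0.01 on its other probe, and the neuronal tubulin TUBB3 rose by 0.72 ± 0.14; the TUBB3 call was lost without any 1 tumour, at adjusted p from 0.051 to 0.19. The neuronal list had a median of 0.16 (camera adjusted p = 0.10), and passed with 16 added to the processed values (0.033) and without H187 replicate 2 (0.0098). With an estimated correlation it had adjusted p = 0.88, and with fry 0.40. Its median was -0.0029 without H187 replicate 1, 0.082 without H187-63AR replicate 2 and 0.071 with an offset of 50.

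Of 18 tested genes of the ATF4 and amino acid stress response, 5 were lower in H187-63AR, none higher and 13 did not pass, and 7 were lower adjusted over the list alone. The list's median was -0.32 (camera with preset correlation, adjusted p = 6.2e-06). With an estimated correlation camera gave adjusted p = 0.88, or 0.052 before adjustment over the lists. That test had few residual degrees of freedom and little power, so it does not decide. The preset p does not measure the spread between tumours. The estimated correlation of the members was 0.049, above the preset 0.01, so the preset p may be too small. Fry, which tests whether members move on balance 1 way, gave adjusted p = 0.19. TRIB3, a pseudokinase induced by ATF4, changed by -1.68 ± 0.16 (limma adjusted p = 0.0025), PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, by -1.36 ± 0.20 (other probes -1.05 and -0.59), ATF5 by -1.32 ± 0.23 and CEBPB by -1.03 ± 0.13. The fifth was PSAT1 of serine synthesis at -0.78 ± 0.16, named after its value was seen to complete the count; its call was lost whichever tumour was left out. PCK2 was not past the threshold without H187 replicate 1 (adjusted p = 0.063), nor ATF5 without either H187-63AR tumour (adjusted p = 0.11 without replicate 1 and 0.095 without replicate 2).

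Heat shock genes included 3 lower members among 12 and none higher, with 5 lower and 1 higher adjusted over the list alone. The small heat shock protein gene HSPB1 changed by -1.46 ± 0.24, and the near-identical HSP70 genes HSPA1A and HSPA1B by -1.35 ± 0.21 and -1.22 ± 0.21. The camera test gave adjusted p = 0.079 for this list at a median of -0.17, and passed with median scaling (0.025), with 16 added to the processed values (0.013) and without H187 replicate 2 (8.2e-04). With an estimated correlation it had adjusted p = 0.88, and with fry 0.50. Its median was -0.31 without H187 replicate 2, -0.10 without H187 replicate 1 and -0.28 without H187-63AR replicate 2. Each of the 3 calls depended on single tumours: HSPA1A and HSPA1B lost it without H187 replicate 1 (adjusted p = 0.071 and 0.096) and without H187-63AR replicate 2 (0.087 and 0.099), and HSPB1 without H187-63AR replicate 1 (0.062) or replicate 2 (0.10). None of 18 endoplasmic reticulum stress genes passed over all genes, with MANF at 0.70 ± 0.15 (limma adjusted p = 0.054); adjusted over the list alone 2 were higher and 1 lower. None of 23 hypoxia genes passed, with VEGFA at -0.59 ± 0.15 (adjusted p = 0.093). The hypoxia list had a median of -0.19 (camera adjusted p = 0.079; adjusted p = 0.92 with an estimated correlation and 0.68 with fry), which was -0.49 without H187 replicate 2 (adjusted p = 6.9e-06) and 0.022 without H187 replicate 1 (adjusted p = 0.94), so its direction depended on which H187 tumour was kept. Without H187-63AR replicate 2 it was -0.050. It also passed without H187-63AR replicate 1, at -0.44 (2.0e-04), with median scaling (0.021), with cyclic loess (0.048), with the stricter detection filter (0.045) and with 16 added to the processed values (0.013), each at the preset correlation.

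The list of genes regulated by NF-kB had a median log2 fold change of 0.31 (camera with preset correlation, adjusted p = 0.0018). With an estimated correlation camera gave adjusted p = 0.88, or 0.084 before adjustment, with the same low power. That correlation was 0.065, above the preset 0.01, so here too the preset p may be too small. Fry gave adjusted p = 0.19. The median was 0.15 with an offset of 50, 0.16 with no background correction, 0.19 with no detection filter and 0.47 with the floored values or the stricter filter, with the list called in each. Of 19 members on the array 11 were tested. RELB, CXCL2, CXCL8, CCL20, IL6 and BCL2A1 were not detected on any array, and ICAM1 and TNF on at most 1. The list value therefore does not cover these genes. Of the 11 tested, 1 was higher over all genes and 5 adjusted over the list alone, with none lower in either. The called member was CXCL1, a neutrophil-attracting chemokine, which rose by 1.35 ± 0.16 (limma adjusted p = 0.0054). Among MHC class I genes 1 of 9 rose, HLA-B by 1.69 ± 0.18 (adjusted p = 0.0041), whose value is uncertain because related HLA genes are near-identical in sequence. Of 17 interferon response genes 2 were higher and none lower, and adjusted over the list alone 5 were higher and 1 lower. IFI35 rose by 0.90 ± 0.16 and ISG20 by 0.81 ± 0.17. ISG20 lost its call without any 1 tumour, at adjusted p from 0.060 to 0.21, and IFI35 without any but H187 replicate 1, at adjusted p from 0.072 to 0.11. None of 4 MHC class II genes passed, with HLA-DQB1 at 0.18 ± 0.19, which read 0.44 without H187 replicate 1 and -0.070 without H187 replicate 2.

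**Figure D3:**
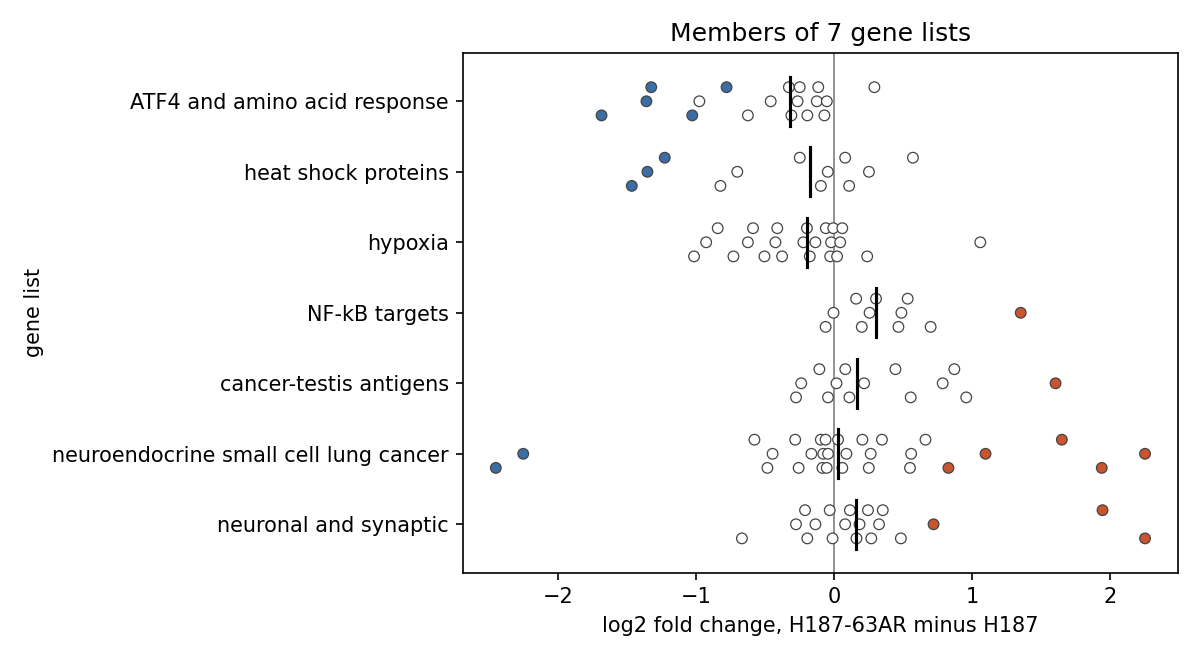
Log2 fold change, H187-63AR minus H187, of each tested member of 7 gene lists; each point is a gene, filled orange where higher, filled blue where lower and open where it did not pass the test, and the black bar is the median of the list. The medians lie at -0.32 for the ATF4 list and 0.31 for the NF-kB list, and the neuroendocrine list has called members on both sides of 0; fitted values are drawn for genes undetected in 1 group.

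GPX2, a glutathione peroxidase, rose by 2.01 ± 0.13 (limma adjusted p = 0.0015) as 1 of 12 tested NRF2 and glutathione genes, of which 3 were higher adjusted over the list alone. ABCC4, a drug efflux transporter, was 1 of 6 in its list and at least 1.48-fold higher, being undetected in H187 (adjusted p = 0.035); its call was lost without H187 replicate 1 (adjusted p = 0.16) or H187 replicate 2 (0.068). ABCB1 and ABCG2 were not detected on any array. Of 14 cancer-testis antigen genes 1 was higher over all genes and 4 adjusted over the list alone, with CTAG2, which has a near-identical relative, at 1.61 ± 0.20 (adjusted p = 0.0072) and 0.54 on its other probe. Of 16 HOX genes HOXB9 rose by 1.48 ± 0.26 and HOXB7 by 0.93 ± 0.15 while HOXB6 read -0.86 ± 0.14, with its other probe at 0.46 and the mean of both at -0.20 (adjusted p = 0.48). Adjusted over the list alone 3 HOX genes were higher and 3 lower. HOXB7 and HOXB6 each kept the call without only 1 of the 4 tumours, at adjusted p up to 0.092 and 0.13, and HOXB9 lost it without H187 replicate 1 (0.074) or H187 replicate 2 (0.054), with an offset of 50 (0.074) or with no background correction (0.054).

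Signalling and growth lists held few calls. In the Notch list 2 of 13 were lower and 3 adjusted over the list alone, DLK1 as above and the effector gene HES5 at -1.10 ± 0.17 (limma adjusted p = 0.017), which was not past the threshold without H187-63AR replicate 1 (adjusted p = 0.082). In the PI3K and insulin-like growth factor list 2 of 11 were lower and 4 adjusted over the list alone. IGFBP5, a growth factor-binding protein, changed by -1.10 ± 0.15 (adjusted p = 0.0099; 0.056 without H187-63AR replicate 2), and FOXO1 was at least 1.40-fold lower, being undetected in H187-63AR (adjusted p = 0.025; 0.12 and 0.095 without H187-63AR replicate 1 and replicate 2). Among MYC targets 1 of 23 was lower, the spermidine synthase SRM at -0.99 ± 0.18 (adjusted p = 0.029), a call kept without H187 replicate 2 and lost without any other tumour, at adjusted p from 0.070 to 0.13. None of 9 MYC family genes passed, and MYC itself was not detected.

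In the remaining tumour and growth lists no gene passed over all genes, and the member with the smallest p is given for each. These were RRM1 at 0.52 ± 0.14 among 23 G1/S genes, CCNB1 at -0.48 ± 0.14 among 25 G2/M genes, CDKN2B at -1.13 ± 0.32 among 8 CDK inhibitor and cyclin genes, ATF3 at -0.72 ± 0.16 among 14 immediate early genes, ETV5 at -0.61 ± 0.20 among 6 MAPK feedback genes, and PTCH1 at -0.37 ± 0.15 of 2 Hedgehog genes. TCF7L2, of 7 Wnt genes, was not detected in H187 and was at least 1.21-fold higher in H187-63AR. SPINT2 read -0.63 ± 0.17 among 13 epithelial genes, S100A6 0.57 ± 0.18 among 12 non-neuroendocrine and mesenchymal genes, PCDHB5 0.72 ± 0.16 among 12 adhesion genes and MXD1 -0.36 ± 0.14 in the MYC family. Metabolic lists gave ENO2 at 0.56 ± 0.15 among 17 glycolysis genes, SDHA at -0.60 ± 0.15 among 24 oxidative phosphorylation genes, DHCR7 at 0.55 ± 0.13 among 14 cholesterol synthesis genes and RPLP1 at -0.51 ± 0.15 among 25 ribosomal protein genes. The adjusted p-values of these 15 genes lay between 0.055 and 0.26 (limma). CDKN2B read -0.11 on its other probe, -0.56 without H187-63AR replicate 2 and -1.71 without H187-63AR replicate 1, where it passed (adjusted p = 0.0072), as it did with median scaling (0.031) and with 16 added to the processed values (0.038). ETV5 read -0.40 without H187 replicate 2 or H187-63AR replicate 2, PTCH1 -0.22 without H187-63AR replicate 1 and S100A6 0.36 without H187 replicate 2. Adjusted over the list alone, 2 epithelial genes were lower, 2 immediate early genes higher and 2 lower, 2 adhesion genes higher and 1 lower, and 1 cholesterol synthesis gene higher. The median, the mean and the camera direction of a list differed in sign for some lists without a call, among them the pro-survival list with a median of 0.13, which was -0.027 without H187 replicate 1, and a mean of -0.070.

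Markers of other cells in a xenograft were mostly undetected by these human probes. COL1A1, CDH5, CSF1R and ADIPOQ were not detected on any array, and of the 23 fibroblast and matrix genes 4 were tested. None passed among 4 fibroblast, 6 endothelial, 4 macrophage and leukocyte, 3 lymphocyte and 5 keratinocyte genes, whose leading values included VWF at 0.66 ± 0.25, AIF1 at 0.36 ± 0.16 and CD79B at 0.21 ± 0.14. VWF and AIF1 read 0.30 and 0.19 without H187 replicate 1, and 1.01 and 0.52 without H187 replicate 2, and VWF read 0.42 without H187-63AR replicate 1. FBLN1 was not detected in H187 and was at least 1.16-fold higher in H187-63AR, and SPRR1B was not detected in H187-63AR and was at least 1.34-fold lower there, both without passing. Of 4 skeletal muscle genes ENO3 was lower at -1.54 ± 0.31 (limma adjusted p = 0.042), a call lost without either H187-63AR tumour (adjusted p = 0.14 and 0.15) and at -0.98 without H187 replicate 1 and -2.10 without H187 replicate 2, and of 6 adipocyte genes CFD was lower at -1.20 ± 0.17 (adjusted p = 0.013; 0.053 without H187 replicate 1 and 0.068 without H187-63AR replicate 2). HBA1, the haemoglobin alpha gene and 1 of 2 erythroid genes tested, read 7.39 and 8.95 in the H187 tumours and 12.56 and 9.22 in the H187-63AR tumours on the log2 scale, so H187-63AR replicate 1 had the highest value (adjusted p = 0.19). HBA1 read 1.04 without that tumour, and passed without H187-63AR replicate 2 at 4.41 (adjusted p = 0.015). The erythroid genes HBB, HBG1, HBG2, SLC4A1, AHSP and EPB42 were not detected on any array. What the HBA1 probe measured in these xenografts is therefore uncertain and was not tested. Adjusted over the list alone, 1 erythroid gene was higher, 1 keratinocyte gene higher and 2 lower, and 1 adipocyte gene higher and 1 lower.

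Calls of further named genes depended on the processing. With an offset of 50 in the background correction 15 named genes lost their call, at adjusted p from 0.054 to 0.11 (limma): CEBPD, STMN2, PCSK1N and HOXB9 as given above, and HSPA1A, HSPA1B, HSPB1, ATF5, SRM, FOXO1, ABCC4, IFI35, ISG20, ENO3 and CFD. With no background correction 8 of these lost it, among them FOXO1, ABCC4, ISG20 and ENO3, at adjusted p up to 0.085. The same offset brought further values nearer to 0 by over 1.5 times. Fold changes given as at least hold for the reported setting. With this offset SST read 1.22, MGMT -1.24, ABCC4 0.35 and FOXO1 -0.38 on the log2 scale. Of genes that kept the call, ZNF91 read 1.34, PNMA2 1.16, KCNT1 1.32, DLK1 -1.77, ASTN2 -1.46, FOXA2 -1.56, RTN1 1.14, GDF15 -0.57, HLA-B 1.10 and DCX 1.27, of those that lost it IFI35 0.55, ISG20 0.43 and CFD -0.61, and of uncalled ones ATF3 -0.48, VEGFA -0.29, ETV5 -0.28, PTCH1 -0.16, PMAIP1 -0.16, BIRC2 0.15, VWF 0.32, AIF1 0.23 and CD79B 0.095. The mean of all probes gave DCX 0.97, CTAG2 1.07 and CDKN2B -0.62. The stricter detection filter ended the calls of ISG20 and ENO3 (adjusted p = 0.057 and 0.056), and a trended robust prior that of ENO3 (0.066). Conversely, the trended robust prior called 7 named genes that did not pass in the reported setting, BIK, SPINT2, RRM1, ATF3, MANF, SDHA and PCDHB5, at adjusted p from 0.016 to 0.050. PCDHB5 and ATF3 were also called with median scaling (0.030 and 0.032) and with 16 added to the processed values (0.032 and 0.034), and TCF7L2 and TNFRSF1B with 16 added (0.027 and 0.033). Cyclic loess called PCDHB5 and MANF (0.039 and 0.044), no background correction called MANF (0.049), and PCDHB5 was called without H187 replicate 2 (0.044).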

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

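The value of the floor for the authors' processed values and the alternative that adds 16 to them were chosen after seeing the data, and the other alternatives were planned. No paired analysis was possible because the groups share only 1 replicate number. All of the 343 genes that an alternative tested kept their direction in it, but the alternatives reuse the arrays that chose these genes. The number called did not hold. Changed, higher and lower genes numbered 137, 70 and 67 with normexp and an offset of 50; 216, 108 and 108 without background correction; 204, 108 and 96 with detection p under 0.01 on all 4 arrays, which tested 244 of the 343; 19, 9 and 10 without a detection filter, where 2647 genes had an unadjusted p under 0.05; 525, 278 and 247 with a trended robust prior; 685, 352 and 333 at adjusted p under 0.1; and 174, 91 and 83 with a 2-fold minimum. Against 343, median scaling called 470, cyclic loess 428 and the mean of probes 314. With the processed values floored at 16, limma called 0, 0 and 0, although 1796 genes, 320 of the 343 among them, had an unadjusted p under 0.05. With 16 added instead it called 545, 293 and 252, sharing 342 with the 343. Degrees of freedom per gene were 7.93 in the reported setting, 2.63 with the floor, where 16.5% of values lay at it, 4.57 without the filter and 11.6 with 16 added; beyond these values the cause was not tested.

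Leaving out 1 tumour, with the lone tumour assumed to vary like the other group, gave 120 to 332 changed, 64 to 174 higher and 48 to 158 lower genes. Of the 343, 113 were called without H187 replicate 1, 209 without H187 replicate 2, 124 without H187-63AR replicate 1 and 101 without H187-63AR replicate 2. The lowest correlation within a group exceeded the highest between groups by 0.0104, by 0.0059 without a detection filter and by 0.0096 to 0.0185 without 1 tumour.

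The number of lists past the threshold, 2 by camera with a preset correlation, was 6 with median scaling and 8 with 16 added to the processed values. It also varied with 1 tumour left out, and was 0 with an estimated correlation or with fry. The preset test had 11 lists at an unadjusted p under 0.05. The ATF4 and NF-kB lists were called in each of the processing alternatives, all at the preset correlation. The trended robust prior does not enter this test, so that alternative could not differ. Without any 1 tumour their medians kept their direction. Lists called in addition were hypoxia, heat shock, cancer-testis and ribosomal protein genes with median scaling and with 16 added, which also called neuronal and fibroblast genes; hypoxia with cyclic loess and the stricter filter; ribosomal protein genes with the floor; and G1/S genes without a filter. Leaving out H187 replicate 1 added NRF2, interferon (adjusted p = 9.4e-05), MHC class I, cancer-testis, glycolysis (0.033) and cholesterol genes, H187 replicate 2 hypoxia, heat shock and neuronal genes (0.0098), and H187-63AR replicate 1 CDK inhibitor, PI3K, hypoxia and cancer-testis genes. The cause was not tested.

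Some medians of lists not called in the reported setting changed sign, in settings where they were not called either. The glycolysis median, 0.046, was -0.038 with median scaling, -0.057 with the floored values and -0.049 with 16 added. The neuroendocrine median, 0.030, was -0.0040 with the floored values, -0.042 without a filter and -0.0030 with 16 added. The lymphocyte median was 0.052 with the floor and 0.019 with 16 added. Without a filter medians were 0.014 for BH3-only, 0.0088 for the MYC family, 0.010 for Hedgehog, -0.049 for efflux, -0.0025 for MHC class I and 0.0014 for MHC class II genes. With the stricter filter they were 0.077 for BAX-type, -0.019 for death receptor and 0.30 for adipocyte genes, and with the mean of probes 0.028 for the MYC family. With 16 added, BCL2L14 and the BAX-type median were 0.062 and MHC class II 0.079. The cause was not tested.

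Without 1 tumour, 8 uncalled genes changed sign: MCL1 ranged from -0.062 to 0.39, BAK1 from -0.23 to 0.053, BAX from -0.11 to 0.26, BCL2L13 from -0.015 to 0.23, BCL2L14 from -0.060 to 0.0084, BBC3 from -0.048 to 0.11, BNIP3 from -0.49 to 0.15 and HLA-DQB1 from -0.070 to 0.44. List medians that did so, some of them called at the other end of the range as given above, ranged from -0.027 to 0.16 for pro-survival, -0.11 to 0.053 for BAX-type, -0.14 to 0.055 for BH3-only, -0.021 to 0.16 for death receptor, -0.064 to 0.23 for non-neuroendocrine, -0.068 to 0.032 for MYC family, -0.060 to 0.0083 for G2/M, -0.12 to 0.0095 for p53, -0.23 to 0.075 for Wnt, -0.49 to 0.022 for hypoxia, -0.16 to 5.4e-04 for endoplasmic reticulum stress, -0.17 to 0.10 for efflux, -0.19 to 0.29 for interferon, -0.084 to 0.16 for MHC class II, -0.11 to 0.16 for HOX, -0.15 to 0.20 for glycolysis, -0.0029 to 0.24 for neuronal, -0.11 to 0.065 for adhesion, -0.21 to 0.36 for endothelial and -0.26 to 0.20 for lymphocyte genes. Medians that kept their sign and moved by over 1.5 times ranged from 0.015 to 0.20 for neuroendocrine, 0.055 to 0.13 for caspase, 0.0046 to 0.091 for inhibitor of apoptosis, -0.39 to -0.089 for epithelial, -0.20 to -0.069 for CDK inhibitor, -0.20 to -0.12 for immediate early, -0.21 to -0.026 for MAPK feedback, -0.18 to -0.016 for PI3K, -0.13 to -0.047 for Notch, -0.40 to -0.17 for Hedgehog, -0.31 to -0.10 for heat shock, 0.0033 to 0.19 for NRF2, 0.032 to 0.14 for MHC class I, 0.13 to 0.31 for cancer-testis, -0.12 to -0.014 for oxidative phosphorylation, 0.050 to 0.27 for cholesterol, 0.25 to 0.56 for fibroblast, 0.13 to 0.33 for macrophage, 0.97 to 3.50 for erythroid, -0.48 to -0.10 for skeletal muscle, -0.22 to -0.018 for keratinocyte and -0.15 to -0.051 for adipocyte genes. Each of these alternatives has fewer samples, and the cause was not tested further. Signal over background limits dim genes, whose changes the offset understates.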

Other observations

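The tests of a mixed H187 sample, its simulations, the reading of the noise test against the other arrays, the spread set on the chromosome 18 median, the tests of copies of chromosome 18, and the gene families described last, were chosen after the results were seen. The plan fixed before the data were examined also held no test of noise on a single array, of chromosomes, of neighbouring genes or of splits of the arrays. Chromosome 18 was singled out from these same data.

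H187 replicate 2 lay nearer to the H187-63AR tumours than H187 replicate 1 did: across genes, the difference between the H187 replicates correlated with the group difference at r = 0.225, against -0.0089 for the H187-63AR replicates. Of 91 called genes at least 2-fold higher in H187-63AR, 30.8% were lower in replicate 2 than in replicate 1, and 1 mixture at the median share of 5.24% with the noise of the H187-63AR replicates gave 17.6 to 35.2% in simulation, so this share leaves H187-63AR material mixed into H187 replicate 2 open; a limit set without this noise had been too strict. Shares of single genes included -19.7% for MT1G, -17.6% for HLA-B, 25.6% for STMN2 and 27.6% for PCSK1N, and the quartiles over the 91, -1.85 and 14.3%, lay 16.2 points apart against 9.09 to 15.0 in simulation, so 1 mixture with this noise alone gave less spread than was seen, while a mixture beside other differences between the tumours stays open. Independent noise on the array of H187 replicate 1 also stays open: among genes far from H187-63AR in replicate 2, replicate 2 lay on the H187-63AR side in 50% of 188, but this choice of genes itself lowers the share, to 15.8, 25.5 and 32.0% with the other 3 arrays in that place, so the test does not decide. No biological explanation was tested, since the labels give none for single tumours.

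Genes of chromosome 18 lay lower in H187-63AR, with a median log2 fold change of -0.18 relative to all genes over 140 genes (permutation p = 1e-04, the smallest that 10000 shuffles give; adjusted over 23 chromosomes 3.3e-04); 6 were called lower, GRP and BCL2 among them, and 0 higher. This p treats genes as independent, while neighbours correlated at 0.146 across genes, against at most 0.0235 in shuffled orders. The median was -0.10 without H187 replicate 2 and -0.29 without H187 replicate 1. Other chromosomes also shifted, such as chromosome 13 by -0.10 and chromosome 11 by 0.064. Chromosomes 6, 11, 12, 13, 16 and 19 had the same permutation p, so it does not single out chromosome 18. The processing stays open as a cause: the median was -0.064 ± 0.022 without a detection filter, which adds undetected genes, and -0.12 or lower in the other alternatives. Variation between tumours of a group stays open, because the H187 replicates differed by 0.19 in this median, as much as the groups. Fewer copies of the chromosome in H187-63AR may also contribute: 3 of 4 stretches had medians of -0.23, -0.18 and -0.19, but the other, at -0.087 ± 0.045, lay within 2 standard errors of 0.

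The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05. The real groups gave 343 genes, and 1 of the 3 splits, the real one, gave as many. The highest of the others was 0 by limma, with 173 and 127 genes at an unadjusted p under 0.05 against 2019. Each other split puts a tumour of either group on each side, so any difference between the groups adds to its residual spread. Few calls there are thus set by the design, and the contrast does not decide.

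Of 6 tested metallothionein genes 3 were higher in H187-63AR, MT1F, MT1G at 1.61 ± 0.20 and MT3 at 1.61 ± 0.19, and MT1X and MT2A read 0.87 and 0.70 without passing. MT1E, undetected in H187, was at least 1.10-fold higher without passing. Of 8 tested pancreatic enzyme genes 4 were lower, the trypsin genes PRSS1, PRSS2 (-2.10 ± 0.19) and PRSS3, and CEL. Among 9 tested SOX factors, SOX11 rose by 1.07 ± 0.15, SOX4 and SOX9 read -1.09 ± 0.16 and -0.87 ± 0.14, and SOX21, undetected in H187-63AR, was at least 1.58-fold lower (limma adjusted p from 0.0085 to 0.021 for the 4). Of the fits without 1 tumour that tested them, SOX11 and SOX9 were called in 1 of 4, SOX4 in 2 of 4 and SOX21 in 1 of 2. The relatives within the metallothionein and trypsin families are near-identical, so their separate values are uncertain.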
